A study of Mus musculus with 36 samples.

How the data were processed

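RNA was measured in CD4 T cells of C57BL/6 mice differentiated in culture. Per the labels' protocols, naive cells (CD44- CD62L+ CD25-) were sorted from the spleen, activated on plates coated with antibodies against CD3 and CD28, and given cytokines for Th17p (pathogenic Th17), Th17n (non-pathogenic Th17) or iTreg (induced regulatory T) cells. The cultures were kept with or without 100 µM DFMO and harvested at 68 h, and live cells were sorted before full-length RNA libraries were made and sequenced as read pairs. There were 36 samples, which are 18 libraries sequenced in 2 runs each, from 3 animals. The labels carry an animal number, so the 6 libraries of an animal form a set and the replicates of a group are separate animals.

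Per the submitters' processing notes, reads were processed with Bowtie2 and RSEM on the genome build GRCm38.p3. Tool versions, the annotation and the strand of the libraries are not given in the sources used here. The deposited count table holds expected counts (estimated read counts per gene and run, without normalization), of which 12.2% are not whole numbers. The deposited second table holds TPM (length-scaled transcript shares made by the authors, per run). Each table has 36 columns and 20817 gene symbols, and 0 columns were left unmatched to a sample. Symbols stand in capitals and were matched to GENCODE M21 names regardless of case, which gave 20079 matches, 20051 of them with 1 location. The listed genes make up between 72.4% and 80.5% of the full TPM scale in a library, so part of each total lies in genes outside the table, which are not analysed here.

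The runs of a library differed by little more than counting error. The chi-square per degree of freedom was between 1.15 and 1.54 for run 1 against run 2 of a library (genes with at least 20 counts in sum), and between 3.64 and 12.1 for animals of a group within run 1. Estimated counts of both runs were therefore summed per library and then rounded. Depth was between 8307633 and 13986923 counts per library. Counting intervals and floors cover counting error only, since the reads carry no molecular identifiers.

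Each gene was tested in edgeR 4.0.16 (R 4.3.3) with 1 robust quasi-likelihood fit of all 18 libraries, a mean per group, TMM scaling and the default filter on low counts by group. This left 11526 genes. P values are two-sided, were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. Levels are CPM (counts scaled to library totals of equal size) with the standard deviation (SD) over 3 animals. Comparisons were DFMO against vehicle in each lineage, the lineages against each other in vehicle, and the difference between the DFMO effects of each pair of lineages. The fit has no term for the animal. A fit with the animal as a block was an alternative, since libraries of 1 animal resembled each other after group means were removed (median r 0.121 over 45 pairs, against -0.063 over 90 pairs of different animals).

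Fixed gene lists (30 lists, 547 genes named, 536 found) were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. The 25 lists with at least 5 tested members entered the test, adjusted by Benjamini-Hochberg within a comparison, and a correlation estimated per list was an alternative. The lists are polyamine metabolism, Treg signature, Th17 signature, pathogenic Th17, non-pathogenic Th17, Th1, Th2, interferon response, TGF-beta response, IL-6 STAT3 and IL-2 STAT5 targets, TCR early response, co-inhibitory receptors, naive and memory, S phase, G2 and M phase, p53 targets, amino acid response (ATF4), unfolded protein response, glycolysis, TCA cycle and OXPHOS, fatty acid oxidation, cholesterol synthesis, histone demethylases and polycomb, ribosome biogenesis and hypoxia response, and markers of B cells, CD8 T cells, NK and innate lymphoid cells, myeloid cells, and erythroid cells and platelets. Genes called between iTreg and a Th17 lineage with an absolute log2 fold change of at least 1 formed lists that were tested in the other Th17 lineage, so that list and test share no library.

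The groups, tests, lists, alternatives and the rule for naming genes were set before the data were examined. Named genes are the 8 called genes with the largest increase and the 8 with the largest decrease per comparison (mean log2 CPM of at least 2, the same sign in all 3 animals, without predicted genes, histones and antigen receptor segments), 21 genes chosen whatever their result, up to 4 members per list with the smallest p, and the 8 largest differences between DFMO effects. Results of some of these genes, and a test on a pair of similar genes, are not reported here. Where a group had 1 to 3 counts in all, a gene's ratio of counts is given with its 95% counting interval, and where it had no count, the bound against a floor of 3 counts.

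The alternatives were RLE scaling, no filter, DESeq2 1.42.0, limma-trend on log2(TPM + 1), the animal as a block, each run alone, a fit of the compared groups alone, and leaving out each animal and each library. Library totals without scaling factors were added after seeing the data. Group labels were permuted over other splits of the libraries. The analysis was tested on simulated data in which known genes were changed. Of genes changed 2-fold, 82.1%, 83.6% and 89.6% were called in the Th17p, Th17n and iTreg designs, of genes changed 1.5-fold 38.8%, 43.3% and 44.8%, and between 3.25% and 5.16% of the calls were false. Only 66 or 67 genes per fold were changed, none of them of low level, in 1 group at a time. The simulated groups were otherwise alike, without an effect of the animal. In the real data 32.9% to 46.4% of genes were called for DFMO, so these rates need not hold there. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and plots.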

Results

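Gene expression was measured by full-length RNA sequencing in mouse CD4 T cells driven towards 3 fates in culture. Naive CD4 T cells of 3 C57BL/6 mice were activated through CD3 and CD28. Pathogenic Th17 cells (Th17p) received IL-6 at 25 ng/ml with IL-1b and IL-23 at 20 ng/ml each. Non-pathogenic Th17 cells (Th17n) received IL-6 at 25 ng/ml with TGF-beta 1 at 2 ng/ml, and induced regulatory T cells (iTreg) TGF-beta 1 at 2 ng/ml without IL-6. Th17 cells are helper cells that secrete IL-17, and iTreg cells are suppressive cells that depend on the transcription factor Foxp3. Each lineage was grown for 68 h with vehicle or with 100 µM DFMO (difluoromethylornithine), an inhibitor of ornithine decarboxylase (Odc1), the enzyme that starts polyamine synthesis. Each of the 6 groups holds 3 libraries, 1 from each animal, with 8307633 to 13986923 estimated counts per library.

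Changes are log2 fold changes ± standard error (SE) from edgeR with n = 3 animals per group, and "rose", "fell", "higher" and "lower" are used for a gene at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test. List tests are camera's, adjusted over 25 lists. Positions are on GRCm38.

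The libraries separated by lineage and by treatment. The first principal component of log2 CPM held 38.6% of the variance and the second 18.1%. On the first, vehicle libraries of Th17p and Th17n lay between -60.7 and -46.6 and their DFMO libraries between -13.0 and 17.9. Vehicle iTreg libraries lay between 20.9 and 35.7 and DFMO iTreg libraries between 75.3 and 82.2.

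**Figure D1:**
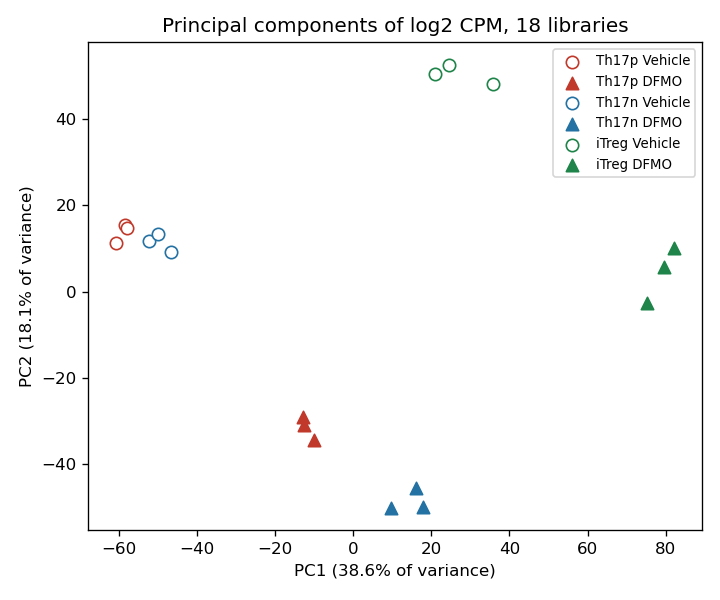
Scores of the 18 libraries on the first and second principal components of log2 CPM, with open circles for vehicle, filled triangles for DFMO and a colour per lineage. DFMO libraries lie to the right of and below the vehicle libraries of their lineage.

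Markers of other cell types were low apart from single genes. Summed over the list, B cell markers were 5.97 CPM in vehicle and 2.01 CPM in DFMO Th17p cells, 7.58 and 2.70 CPM in Th17n cells, and 17.5 and 19.7 CPM in iTreg cells. Most of it was Cd79b, a subunit of the B cell receptor. Of the 4 tested B cell markers, Cd79b fell by 2.00 ± 0.46 with DFMO in Th17p cells and by 1.68 ± 0.34 in Th17n cells. It lost its call in Th17p cells with run 2 alone (-1.29). CD8 T cell markers (4 tested) summed to 24.8 CPM in vehicle and 17.9 CPM in DFMO Th17p cells, 21.8 and 12.3 CPM in Th17n cells, and 22.2 and 16.2 CPM in iTreg cells. Most of it was Cd8b1, a chain of the CD8 receptor, which fell by 0.79 ± 0.23 in Th17n cells (not called without animal 3, -0.73) and did not pass in the others (called in iTreg cells on log2 TPM, -0.54). NK and innate lymphoid markers summed to between 0.978 and 5.05 CPM (2 tested), and erythroid and platelet markers to between 0.122 and 0.765 CPM (none tested). Myeloid markers summed to 120 and 102 CPM, 113 and 108 CPM, and 104 and 83.6 CPM in the same order, most of it Cst3, which was the tested member and did not pass with DFMO in any lineage. The share of the full TPM scale that falls on listed genes was 75.9% ± 1.40 (SD, n = 3) in vehicle and 79.9% ± 0.62 in DFMO Th17p cells, 73.8% ± 1.15 and 77.6% ± 0.59 in Th17n cells, and 73.9% ± 1.36 and 76.6% ± 1.67 in iTreg cells. Exact two-sided permutation tests gave p = 0.1, 0.1 and 0.2, where 0.1 is the smallest p that 3 against 3 libraries allow.

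The first comparison asks how the Th17 lineages differed without inhibitor. Il9, a cytokine gene, was 6.04 ± 0.34 higher in Th17n than in Th17p cells, and Maf, a transcription factor of IL-10 producing T cells, 3.76 ± 0.46 higher. Foxp3 (chromosome X, 7573644 to 7595245) was 3.75 ± 0.56 higher, at 0.784 ± 0.74 CPM in Th17p and 11.4 ± 0.40 CPM in Th17n cells (SD). The protease gene Gzmb (-4.45 ± 0.60), its inhibitor Serpinb9 (-5.67 ± 0.30) and Il23r (-3.17 ± 0.26), the receptor for IL-23, were lower. The adjusted p from edgeR's quasi-likelihood test was at most 0.00045 for these genes. In all, 1091 genes were higher and 1212 lower in Th17n cells.

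Of 17 pathogenic Th17 genes 13 were lower in Th17n cells (14 adjusted over the list alone), among them Icos (-1.48 ± 0.09). Of 9 non-pathogenic Th17 genes 6 were higher (6 adjusted over the list alone), among them Ahr (3.08 ± 0.30) and Ikzf3 (1.69 ± 0.16). The camera adjusted p was 6.0e-09 and 2.1e-06. Unfolded protein response genes were lower in 13 of 16 cases (14 adjusted over the list alone, camera adjusted p = 2.0e-13), as the chaperone Hspa5 (-1.42 ± 0.08) and the factor Manf (-1.24 ± 0.09). In the Treg signature 10 of 24 were higher and 2 lower (12 and 2 adjusted over the list alone, camera adjusted p = 0.0013), including Ikzf4 (1.24 ± 0.12). These lists kept their call with an estimated correlation, at an adjusted p of 0.011, 0.011, 0.011 and 0.018.

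The call of 9 further lists between Th17n and Th17p cells was lost with an estimated correlation. Interferon response genes were lower in 19 of 30 cases (25 adjusted over the list alone, camera adjusted p = 1.0e-11, adjusted p = 0.093 with an estimated correlation), with Gbp4 at -2.67 ± 0.28 and Mx1 at least 37.9-fold lower. Of 30 G2 and M phase genes 23 were higher (27 adjusted over the list alone, camera adjusted p = 2.4e-13, adjusted p = 0.062 with an estimated correlation), such as Ckap2l (0.68 ± 0.08). Of 19 p53 targets 10 were lower (11 adjusted over the list alone, camera adjusted p = 1.4e-05, adjusted p = 0.093 with an estimated correlation), such as Mdm2 (-0.80 ± 0.10). Of 24 ribosome biogenesis genes 14 were lower and 1 higher (17 and 1 adjusted over the list alone, camera adjusted p = 2.8e-05, adjusted p = 0.20 with an estimated correlation), such as Nolc1 (-0.73 ± 0.09). TGF-beta response genes were higher in 6 and lower in 1 of 12 cases, also adjusted over the list alone (camera adjusted p = 0.0023, adjusted p = 0.093 with an estimated correlation), with Id1 at 2.78 ± 0.30. Th1 genes were lower in 5 of 12 cases (6 adjusted over the list alone, camera adjusted p = 0.0038, adjusted p = 0.093 with an estimated correlation), with Cxcr3 at -2.38 ± 0.20. Co-inhibitory receptors were lower in 4 and higher in 1 of 10 cases, also adjusted over the list alone (camera adjusted p = 0.0077, adjusted p = 0.21 with an estimated correlation), with Tigit at -2.81 ± 0.33. Amino acid response genes were lower in 5 and higher in 1 of 26 cases (9 and 1 without scaling factors, 7 and 1 adjusted over the list alone, camera adjusted p = 0.025, adjusted p = 0.61 with an estimated correlation). Of 21 cholesterol synthesis genes only Srebf2 was higher (none adjusted over the list alone, camera adjusted p = 0.041, adjusted p = 0.66 with an estimated correlation), at 0.30 ± 0.10, and without animal 1 or animal 2 it was not called (0.28 and 0.27). With the animal as a block, 3 more lists were called, polyamine metabolism (1 higher and 4 lower of 18, adjusted p 0.077 and 0.033 blocked), the Th17 signature (11 and 5 of 22, 0.062 and 0.046) and TCR early response (4 and 6 of 18, 0.083 and 0.046). Without scaling factors camera also called the Th17 signature (adjusted p = 0.026), IL-6 STAT3 and IL-2 STAT5 targets (0.042, 0.062 with scaling), S phase (0.040, 0.078 with scaling) and hypoxia response (0.042, 0.063 with scaling). The count of genes fell to 1346 without animal 1 and to 944 without animal 2, and the split was 822 higher and 1571 lower without scaling factors and 645 and 1781 on log2 TPM.

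The next comparisons set vehicle iTreg cells against each Th17 lineage. Foxp3 was 5.26 ± 0.36 higher in iTreg than in Th17n cells and 9.01 ± 0.48 higher than in Th17p cells, at 435 ± 70.2 CPM (SD). The cytokine genes of Th17 cells were far lower in iTreg cells. Il17a (chromosome 1, 20730905 to 20734496) was 3507-fold lower than in Th17n cells (95% counting interval 971 to 28967) and 6514-fold lower than in Th17p cells (1803 to 53793), with 2 counts over the iTreg libraries. Il17f (chromosome 1, 20777146 to 20790617) was at -9.09 ± 0.58 and -10.03 ± 0.59. Il21 was 3861-fold lower (1068 to 31888) and 1962-fold lower (543 to 16205), and Il22 at least 2625-fold lower than in Th17p cells. Il23r, with 1 count in iTreg cells, was 1699-fold lower than in Th17p cells (304 to 67144). The transcription factor Tead1 (4.75 ± 0.48 and 6.30 ± 0.56) and the receptor Nrp1 (4.14 ± 0.43 and 4.36 ± 0.44) were higher in iTreg cells, and the protease inhibitor Timp1 (-11.56 ± 0.55 and -11.10 ± 0.55) lower.

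In iTreg against Th17n cells 2121 genes were higher and 2180 lower. Of 22 Th17 signature genes 16 were lower and 1 higher (19 and 1 adjusted over the list alone, camera adjusted p = 1.4e-12), such as Irf4 (-1.28 ± 0.08) and Hif1a (-1.96 ± 0.13). Of 9 non-pathogenic Th17 genes 7 were lower (8 adjusted over the list alone, camera adjusted p = 4.0e-05), such as Maf (-6.14 ± 0.57). Both kept their call with an estimated correlation, at an adjusted p of 1.8e-04 and 0.039. Interferon response genes were higher in 23 of 30 cases (26 adjusted over the list alone, camera adjusted p = 2.1e-09, adjusted p = 0.29 with an estimated correlation), with Isg20 at 4.65 ± 0.49. S phase genes were higher in 23 of 30 cases (25 adjusted over the list alone, camera adjusted p = 4.5e-09, adjusted p = 0.29 with an estimated correlation), with Tyms at 1.23 ± 0.11. Of 15 targets of IL-6 STAT3 and IL-2 STAT5, 8 were lower and 1 higher, also adjusted over the list alone (camera adjusted p = 0.0060, adjusted p = 0.051 with an estimated correlation), with Socs3, the feedback inhibitor of STAT3 signalling, at -3.87 ± 0.11. Glycolysis genes were lower in 12 of 20 cases, also adjusted over the list alone (camera adjusted p = 4.0e-05, adjusted p = 0.49 with an estimated correlation), such as Hk1 (-1.19 ± 0.09). Hypoxia response genes were lower in 12 of 18 cases, also adjusted over the list alone (camera adjusted p = 6.6e-05, adjusted p = 0.42 with an estimated correlation), such as P4ha2 (-2.29 ± 0.25). Ribosome biogenesis genes were higher in 15 and lower in 2 of 24 cases, also adjusted over the list alone (camera adjusted p = 3.2e-04, adjusted p = 0.42 with an estimated correlation), such as Nop56 (0.84 ± 0.09). TCR early response genes (6 higher and 1 lower of 18) were called with the animal as a block (camera adjusted p 0.081, and 0.046 blocked). TGF-beta response genes were called as lower without scaling factors (camera adjusted p 0.059, and 0.037 without them). Without scaling factors 3184 genes were higher and 1518 lower, with the median of all genes at 0.16, and on log2 TPM 3200 and 1380. The count was 2784 without animal 1 and 2861 without animal 2.

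In iTreg against Th17p cells 1667 genes were higher and 1810 lower. A pair of lists kept their call with an estimated correlation. In the Th17 signature 15 of 22 genes were lower and 4 higher (16 and 4 adjusted over the list alone, camera adjusted p = 1.1e-07, and 0.0027 estimated). In the unfolded protein response 13 of 16 were lower and 1 higher, also adjusted over the list alone (camera adjusted p = 2.8e-09, and 0.047 estimated). Examples are Batf (-1.95 ± 0.13) and Nfkbiz (-1.84 ± 0.12) of the first and Hspa5 (-1.51 ± 0.08) and Pdia6 (-1.20 ± 0.07) of the second. G2 and M phase genes were higher in 28 of 30 cases (29 adjusted over the list alone, camera adjusted p = 2.8e-12, adjusted p = 0.092 with an estimated correlation), such as Mki67 (0.98 ± 0.10), and S phase genes were higher in 22 of 30 (24 adjusted over the list alone, camera adjusted p = 1.1e-07, adjusted p = 0.25 with an estimated correlation). Of 17 pathogenic Th17 genes 10 were lower and 3 higher (12 and 3 adjusted over the list alone, camera adjusted p = 2.8e-04, adjusted p = 0.077 with an estimated correlation), such as Tgfb3 (-4.93 ± 0.37) and Lgals3 (-3.43 ± 0.27). Co-inhibitory receptors were lower in 7 of 10 cases (also adjusted over the list alone, camera adjusted p = 8.2e-04, adjusted p = 0.23 with an estimated correlation), such as Cd200 (-2.07 ± 0.16). Glycolysis genes were lower in 11 of 20 (7 without scaling factors, camera adjusted p = 2.8e-04) and hypoxia response genes lower in 9 and higher in 1 of 18 (camera adjusted p = 0.0034), with the same counts adjusted over the list alone. Cholesterol synthesis genes were higher in 10 of 21 (11 adjusted over the list alone, camera adjusted p = 4.1e-04). Each of these 3 lists had an adjusted p of 0.58 with an estimated correlation. In the Treg signature 13 of 24 were higher and 6 lower, also adjusted over the list alone (camera adjusted p = 0.026, adjusted p = 0.096 with an estimated correlation and 0.070 without scaling factors), such as Lrrc32 (2.10 ± 0.20). Without scaling factors 2174 genes were higher and 1477 lower, and without animal 2 the count was 2289.

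DFMO against vehicle asks which genes respond to a block of polyamine synthesis in each lineage. Several genes of polyamine metabolism moved the same way in each lineage. Amd1 (chromosome 10, 40287458 to 40302186), the decarboxylase that supplies aminopropyl groups for spermidine and spermine, rose by 1.25 ± 0.08 in Th17p, 1.82 ± 0.09 in Th17n and 1.94 ± 0.09 in iTreg cells, in the last from 152 ± 5.98 to 582 ± 59.4 CPM (SD). Azin1, an inhibitor of antizyme, rose by 1.27 ± 0.10, 1.64 ± 0.10 and 0.84 ± 0.10. Antizyme, which marks Odc1 for degradation, is encoded by Oaz1 and Oaz2. Oaz1 fell by 0.86 ± 0.07, 1.29 ± 0.07 and 0.99 ± 0.07 and Oaz2 by 2.08 ± 0.16, 2.76 ± 0.17 and 2.81 ± 0.17. Smox, which oxidises spermine, fell by 1.66 ± 0.22, 2.35 ± 0.23 and 2.21 ± 0.26. The adjusted p from edgeR's quasi-likelihood test was at most 5.3e-05 for these genes in every lineage.

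The target of the drug itself, Odc1 (chromosome 12, 17544794 to 17551505), moved in opposite directions. It rose by 0.67 ± 0.13 in Th17p cells (198 ± 39.1 to 316 ± 3.59 CPM, edgeR adjusted p = 0.00084) and fell by 0.57 ± 0.14 in iTreg cells (163 ± 10.8 to 110 ± 24.5 CPM, edgeR adjusted p = 0.0028). In Th17n cells the change was 0.20 ± 0.13 (edgeR adjusted p = 0.25, and 0.038 in a fit of the compared groups alone). Srm, which makes spermidine, rose in Th17n cells (2.62 ± 0.68), but was not called without animal 1 (2.85) or animal 2 (2.75). In Th17p and iTreg cells it was at 1.58 ± 0.65 and 0.75 ± 0.63 and was called with the animal as a block (edgeR adjusted p 0.083 and 0.0020 blocked, 0.39 and 0.037 blocked) and without animal 3 (1.15 and 0.90). Sms, which makes spermine, rose by 0.48 ± 0.08 in Th17p cells, and at 0.21 ± 0.09 in Th17n and 0.20 ± 0.08 in iTreg cells was called with the block (edgeR adjusted p 0.052 and 0.026 blocked, 0.065 and 0.036 blocked). Sat1, which acetylates polyamines, was at 0.00 ± 1.35, -0.22 ± 1.36 and -0.24 ± 1.36, with a spread between animals of 325 ± 253 CPM in vehicle Th17p cells. With the animal as a block it was at -0.02, -0.05 and -0.21 (edgeR adjusted p = 0.94, 0.82 and 0.29). Over the whole list 9 genes rose and 4 fell of 18 in Th17p cells (10 and 4 adjusted over the list alone), 8 and 4 in Th17n cells (9 and 5), and 6 and 5 in iTreg cells (7 and 5), with a camera adjusted p of 0.17, 0.27 and 0.63.

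**Figure D2:**
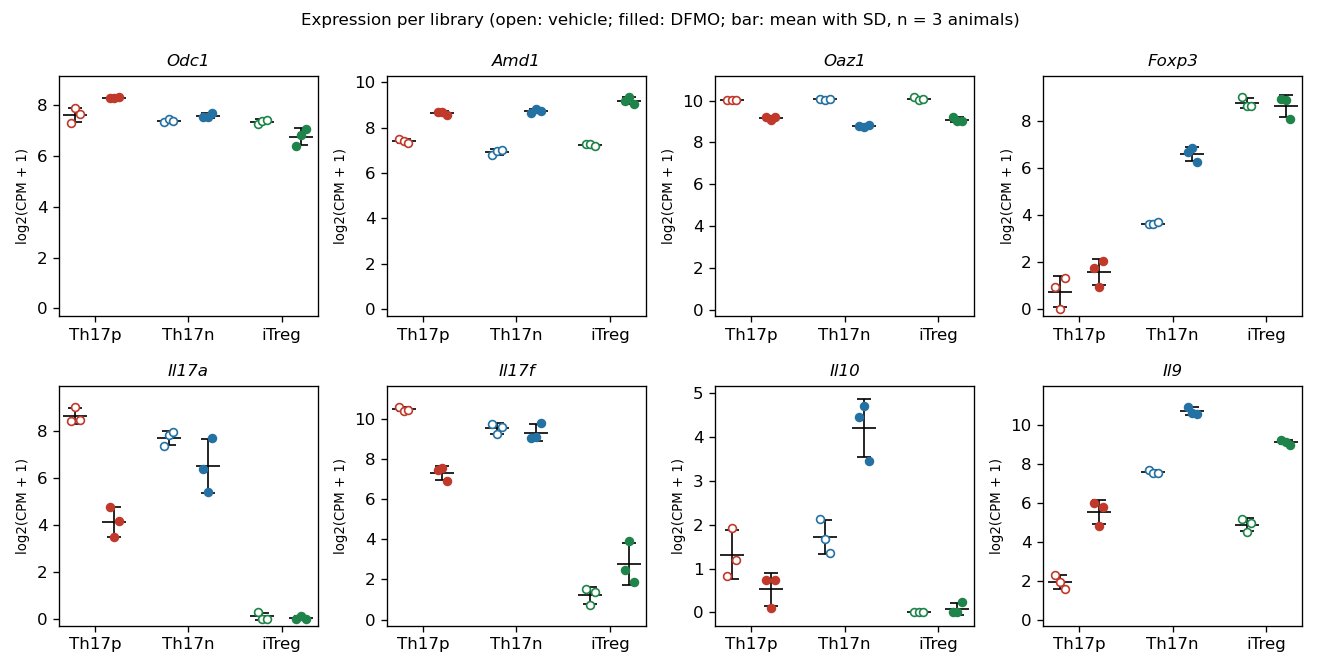
Expression of 8 genes as log2(CPM + 1) per library in each lineage, with open points for vehicle, filled points for DFMO and bars for the mean with its SD over 3 animals. Amd1 is higher and Oaz1 lower with DFMO in all 3 lineages, Foxp3 rises in Th17n cells, and Il17a and Il17f fall in Th17p cells.

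In pathogenic Th17 cells 13 of 22 Th17 signature genes fell with DFMO and the other 9 did not pass. Il17a fell by 4.57 ± 0.55, from 412 ± 103 to 17.7 ± 7.97 CPM (SD, n = 3, edgeR adjusted p = 4.7e-05), and Il17f by 3.15 ± 0.39, from 1420 ± 104 to 160 ± 37.9 CPM (edgeR adjusted p = 5.5e-05). Il23r fell by 2.18 ± 0.24. Il9 was 16.2-fold higher (4.02 ± 0.34, edgeR adjusted p = 2.2e-06) and Il2, the T cell growth factor, 4.84-fold higher (2.27 ± 0.30). The largest decreases included Selenbp1 (-5.21 ± 0.29), Ctla2b (-5.47 ± 0.61) and Irf7 (-4.80 ± 0.61), a transcription factor of the interferon response, and the largest increases the receptor Nrp1 (2.54 ± 0.43) and the chemokine Ccl3 (2.60 ± 0.44). In all, 1827 genes rose and 1970 fell, and 976 of them changed at least 2-fold. Without animal 2 the count was 2416.

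In Th17p cells the Th17 signature, with 13 genes lower also when adjusted over the list alone, kept its call with an estimated correlation (camera adjusted p = 1.1e-04, and 0.031 estimated). Interferon response genes fell in 27 of 30 cases (28 adjusted over the list alone, camera adjusted p = 5.3e-13, adjusted p = 0.30 with an estimated correlation), such as Isg15 (-3.74 ± 0.41) and Stat2 (-1.63 ± 0.16). S phase genes rose in 18 of 30 cases (20 adjusted over the list alone, camera adjusted p = 1.1e-05, adjusted p = 0.37 with an estimated correlation), such as Cdca7 (0.59 ± 0.09). Ribosome biogenesis genes rose in 18 of 24 (also 18 adjusted over the list alone, with 1 lower, camera adjusted p = 7.9e-08, adjusted p = 0.31 with an estimated correlation), such as Rrp9 (0.95 ± 0.09). Of 25 genes of the TCA cycle and OXPHOS 12 rose and 1 fell (14 and 1 adjusted over the list alone, camera adjusted p = 0.0015, adjusted p = 0.37 with an estimated correlation), such as Atp5b (0.51 ± 0.06). Glycolysis genes fell in 14 and rose in 1 of 20 cases (16 and 1 adjusted over the list alone, camera adjusted p = 1.9e-06, adjusted p = 0.37 with an estimated correlation), with the glucose transporter Slc2a3 at -3.08 ± 0.28 and the kinase Pfkm at -1.53 ± 0.17. Hypoxia response genes fell in 13 of 18 cases (17 adjusted over the list alone, camera adjusted p = 3.6e-07, adjusted p = 0.34 with an estimated correlation), such as Bnip3 (-2.26 ± 0.31). Of 18 TCR early response genes 8 rose and 3 fell (8 and 4 adjusted over the list alone, camera adjusted p = 0.026, adjusted p = 0.47 with an estimated correlation), with Egr2 at 1.60 ± 0.18 and Tnf at 1.25 ± 0.10. G2 and M phase genes rose in 7 and fell in 2 of 30 cases (6 and 3 without scaling factors), also adjusted over the list alone, with Cdk1 at 0.46 ± 0.07. Amino acid response genes fell in 11 and rose in 1 of 26 (13 and 1 adjusted over the list alone), with Pycr1 at -1.93 ± 0.20. Both had a camera adjusted p of 0.022, and an adjusted p of 0.47 with an estimated correlation.

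The remaining lists were not called in Th17p cells. Rises and falls stood at 6 and 9 of 24 for the Treg signature (6 and 10 adjusted over the list alone), 2 and 6 of 17 for pathogenic Th17 (2 and 7), 2 and 3 of 9 for non-pathogenic Th17 (2 and 4), and 1 and 2 of 6 for Th2 (2 and 2). They stood at 3 and 1 of 12 for TGF-beta response, 2 and 8 of 15 for IL-6 STAT3 and IL-2 STAT5 targets, 2 and 5 of 10 for co-inhibitory receptors, 1 and 6 of 14 for naive and memory (2 and 6), and 5 and 3 of 19 for p53 targets (6 and 3). For fatty acid oxidation they were 2 and 6 of 17 (2 and 7), for cholesterol synthesis 1 and 2 of 21, and for histone demethylases and polycomb 6 and 5 of 22 (6 and 6, and 3 and 6 without scaling factors), while 6 of 12 Th1 genes fell (7). The unfolded protein response had 7 of 16 genes lower and a camera adjusted p of 0.060, which was 0.046 with RLE scaling and 0.046 without scaling factors. Tgfb3 (-6.25 ± 0.42) and the ectonucleotidase Entpd1 (-4.07 ± 0.46) fell in these lists, as did Ctla4 (-1.19 ± 0.17) and Il2ra (-0.57 ± 0.10), while Ikzf2 rose (1.57 ± 0.35). Foxp3 was at 1.27 ± 0.72 (edgeR adjusted p = 0.20, called by DESeq2 at 0.035), Il10 at -1.82 ± 0.69 (edgeR adjusted p = 0.051, 0.048 with RLE scaling, called without animal 3 at -2.43, and at -0.62 without animal 2), Tbx21 at 0.49 ± 0.39 (0.34 without animal 1, called without animal 3, 0.76, and in a fit of the compared groups alone, 0.47) and the demethylase Kdm6b at 0.03 ± 0.13.

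In non-pathogenic Th17 cells DFMO raised Foxp3 8.53-fold (3.09 ± 0.34), from 11.4 ± 0.40 to 97.2 ± 19.5 CPM (SD, n = 3, edgeR adjusted p = 7.4e-06), while vehicle iTreg cells stood at 435 ± 70.2 CPM. Il10 (chromosome 1, 131019845 to 131024974), an anti-inflammatory cytokine gene, rose 7.90-fold (2.98 ± 0.54, edgeR adjusted p = 0.00019), from 2.39 ± 0.94 to 18.8 ± 7.82 CPM. Il9 rose by 3.12 ± 0.26, Il2 by 3.13 ± 0.32, Nrp1 by 3.11 ± 0.43 and Ccl3 by 4.54 ± 0.61. Il17a and Il17f did not pass, at -0.94 ± 0.47 (edgeR adjusted p = 0.12) and -0.18 ± 0.36 (edgeR adjusted p = 0.70), and Il17a was at -0.49 without animal 2 but called without animal 3 (-1.65) and on log2 TPM (-1.13). Il23r fell by 1.87 ± 0.30. Further falls were those of Tgfb3 (-6.38 ± 0.41), the chemokine Ccl5 (-5.61 ± 0.89, and -10.84 without animal 2), Selenbp1 (-5.12 ± 0.28), the aldolase Aldoc (-5.01 ± 0.24) and the receptor Tnfrsf9 (-4.43 ± 0.27). In all, 2626 genes rose and 2726 fell, 1806 of them at least 2-fold.

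Ribosome biogenesis genes rose in 22 of 24 cases in Th17n cells (22 adjusted over the list alone, with 1 lower, camera adjusted p = 3.6e-11, adjusted p = 0.43 with an estimated correlation), such as Nolc1 (1.47 ± 0.09). S phase genes rose in 23 of 30 (also 23 adjusted over the list alone, camera adjusted p = 5.2e-09, adjusted p = 0.44 with an estimated correlation), such as Rrm2 (1.53 ± 0.11) and Cdc6 (1.37 ± 0.10). TCR early response genes rose in 9 of 18 cases (9 adjusted over the list alone, with 1 lower, camera adjusted p = 0.013, adjusted p = 0.52 with an estimated correlation), such as Egr2 (1.78 ± 0.18). Glycolysis genes fell in 15 and rose in 1 of 20 cases and hypoxia response genes fell in 14 of 18, also adjusted over the list alone, with Gpi1 at -1.18 ± 0.08 and the peptide hormone gene Adm at -3.03 ± 0.37. Both had a camera adjusted p of 1.6e-05 and an adjusted p of 0.52 with an estimated correlation. Interferon response genes fell in 17 and rose in 1 of 30 cases, also adjusted over the list alone (camera adjusted p = 4.6e-04, adjusted p = 0.52 with an estimated correlation), such as Ifih1 (-2.17 ± 0.31). Fatty acid oxidation genes fell in 10 and rose in 1 of 17 cases, also adjusted over the list alone (camera adjusted p = 0.0054, adjusted p = 0.44 with an estimated correlation), such as Hadh (-0.82 ± 0.09). Th1 genes fell in 6 of 12 cases (7 adjusted over the list alone, camera adjusted p = 0.032, adjusted p = 0.44 with an estimated correlation), such as Il12rb2 (-3.38 ± 0.40).

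Lists that were not called in Th17n cells include the Th17 signature (5 rose and 6 fell of 22, camera adjusted p = 0.33), the Treg signature (5 and 7 of 24, 0.47), pathogenic Th17 (2 and 7 of 17, 0.18), non-pathogenic Th17 (5 and 1 of 9, 0.17) and the unfolded protein response (8 and 2 of 16, 0.17), with the same counts adjusted over the list alone. Hspa5 rose by 0.31 ± 0.08 and Calr by 0.69 ± 0.09. Ctla4 was at -0.26 ± 0.16 (-0.14 without animal 2, called without animal 3, -0.48), Il2ra at -0.19 ± 0.10, Ikzf2 at 0.63 ± 0.37, Tbx21 at 0.27 ± 0.46 and Kdm6b at -0.02 ± 0.13.

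In iTreg cells Foxp3 did not pass with DFMO, at 435 ± 70.2 and 411 ± 118 CPM (SD, -0.08 ± 0.28, edgeR adjusted p = 0.85). Il9 rose 19.0-fold (4.25 ± 0.28, edgeR adjusted p = 1.1e-07), from 28.8 ± 6.80 to 546 ± 42.8 CPM. Ctla4, an inhibitory receptor of regulatory T cells, fell by 2.35 ± 0.18, from 208 ± 23.7 to 40.8 ± 1.56 CPM (edgeR adjusted p = 8.7e-08). Gcnt2, a glycosyltransferase, rose by 4.53 ± 0.68 (7.06 without animal 2), Timp1 by 4.10 ± 0.74 and Inhba, a subunit of activin, by 2.53 ± 0.44. The granzyme gene Gzmb fell by 5.55 ± 0.74, Ccl5 by 7.45 ± 1.13, the transglutaminase Tgm2 by 6.10 ± 0.58 and Aldoc by 5.19 ± 0.29. Selenbp1, with 3 counts in DFMO cells, was 98.5-fold lower (counting interval 33.4 to 480). Il17f rose from 1.36 ± 0.63 to 7.04 ± 6.04 CPM (2.42 ± 0.68, edgeR adjusted p = 0.014) and Maf by 2.39 ± 0.66, but without animal 1 or animal 2 neither was called (Il17f 2.88 and 1.02, Maf 2.28 and 1.92). Il17a, Il23r and Il10 had at most 3 counts in both iTreg groups. In all, 2112 genes rose and 2217 fell, 1253 of them at least 2-fold. Without scaling factors, where the median of all genes lies at -0.21, 1284 rose and 3286 fell, on log2 TPM 1024 and 3439, and without animal 2 the count was 2488.

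Glycolysis genes fell in 18 of 20 cases in iTreg cells (18 adjusted over the list alone, camera adjusted p = 1.5e-09, adjusted p = 0.26 with an estimated correlation), such as Pfkp (-1.58 ± 0.14) and Aldoa (-1.38 ± 0.12). Hypoxia response genes fell in 15 of 18 with 1 higher, also adjusted over the list alone (camera adjusted p = 4.2e-07, adjusted p = 0.26 with an estimated correlation), such as P4ha2 (-4.70 ± 0.39). Genes of the TCA cycle and OXPHOS rose in 17 and fell in 1 of 25 cases (10 and 3 without scaling factors, 18 and 1 adjusted over the list alone, camera adjusted p = 1.1e-05, adjusted p = 0.23 with an estimated correlation), such as Sdha (0.70 ± 0.08). Interferon response genes fell in 24 of 30 cases (25 adjusted over the list alone, camera adjusted p = 1.0e-10, adjusted p = 0.23 with an estimated correlation), such as Bst2 (-1.67 ± 0.12). Ribosome biogenesis genes rose in 18 of 24 cases (18 adjusted over the list alone, camera adjusted p = 1.6e-09, adjusted p = 0.23 with an estimated correlation), such as Rrp12 (1.34 ± 0.13). TGF-beta response genes rose in 9 of 12 (9 adjusted over the list alone, camera adjusted p = 9.1e-04, adjusted p = 0.23 with an estimated correlation), such as Id1 (2.21 ± 0.25). Cholesterol synthesis genes fell in 12 of 21 cases (13 adjusted over the list alone, camera adjusted p = 2.7e-05, adjusted p = 0.55 with an estimated correlation), such as Nsdhl (-1.32 ± 0.22). S phase genes rose in 13 and fell in 1 of 30 cases (7 and 4 without scaling factors, 15 and 1 adjusted over the list alone, camera adjusted p = 9.1e-04, adjusted p = 0.55 with an estimated correlation), such as Mcm2 (0.76 ± 0.08). Amino acid response genes fell in 14 and rose in 4 of 26 cases, also adjusted over the list alone (camera adjusted p = 0.023, adjusted p = 0.66 with an estimated correlation), such as Trib3 (-2.75 ± 0.23). Th1 genes fell in 6 of 12 cases (6 and 1 higher adjusted over the list alone, camera adjusted p = 0.021, adjusted p = 0.26 with an estimated correlation and 0.056 without scaling factors), such as Runx3 (-1.77 ± 0.22). Unfolded protein response genes fell in 10 and rose in 2 of 16 cases, also adjusted over the list alone (11 and 0 without scaling factors, camera adjusted p = 0.040, 0.051 with the animal as a block, adjusted p = 0.55 with an estimated correlation), such as Xbp1 (-0.90 ± 0.12).

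Lists that were not called in iTreg cells include the Treg signature (4 rose and 8 fell of 24, 5 and 8 adjusted over the list alone, camera adjusted p = 0.63), in which the receptor Tigit fell by 2.79 ± 0.40 and Ikzf4 rose by 0.81 ± 0.12. The Th17 signature (3 and 3 of 22, also adjusted over the list alone, 3 and 5 without scaling factors, camera adjusted p = 0.77) was not called either. G2 and M phase genes fell in 6 of 30 cases, also adjusted over the list alone (camera adjusted p = 0.30), and without scaling factors in 16 (0.042). Tbx21 fell by 1.45 ± 0.44, but was not called without animal 2 (-1.65) or in a fit of the compared groups alone. Il2ra was at -0.16 ± 0.10 (0.07 without animal 1, called without animal 3 at -0.34, without scaling factors at -0.32 and on log2 TPM at -0.37), Ikzf2 at 0.14 ± 0.32 and Kdm6b at 0.16 ± 0.13. Csf2 and Ifng, cytokine genes of pathogenic T cells, did not pass the filter, with at most 12 and 24 counts in the 3 libraries of a group.

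**Figure D3:**
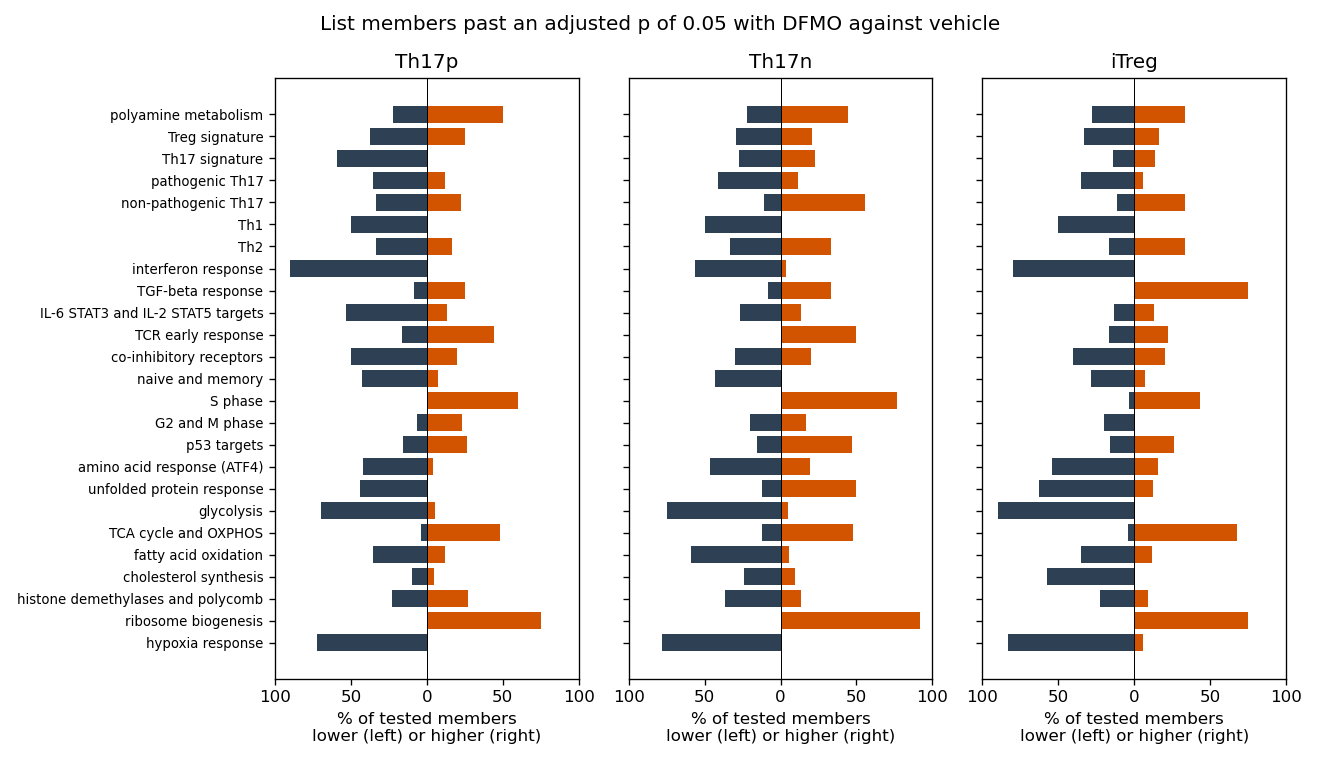
Percent of tested members of each gene list that were lower (left) or higher (right) with DFMO than with vehicle at an adjusted p under 0.05, in each lineage. Ribosome biogenesis and S phase genes lie mostly to the right and glycolysis, hypoxia and interferon response genes to the left in all 3 lineages.

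Responses to DFMO were shared between lineages to a large part. Of 11526 genes, 1412 rose in both Th17n and Th17p cells, where 416 would be shared if the calls were independent, 1512 fell in both (466 if independent), and 33 were called in opposite directions. For Th17n and iTreg cells 1421 rose (481), 1411 fell (524) and 126 were opposite, and for Th17p and iTreg cells 1122 rose (335), 1084 fell (379) and 105 were opposite. In all 3 lineages 988 genes rose, Il9, Amd1, Azin1 and Tnf among them, and 951 fell, such as Oaz1, Smox, Ccl5 and Stat2. Across genes, which are not independent replicates, Pearson's correlation of the DFMO effects was 0.706 for Th17n and Th17p, 0.607 for Th17n and iTreg and 0.496 for Th17p and iTreg cells. Taken animal by animal it was 0.557 ± 0.014, 0.476 ± 0.049 and 0.390 ± 0.060 (SD, n = 3). These comparisons share no library.

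Genes that set iTreg cells apart from Th17 cells were then followed in DFMO-treated Th17 cells. In Th17n cells the 724 genes lower in iTreg than in Th17p cells had a median change of -1.07, with 405 lower and 38 higher (camera p = 4.6e-17, and 3.7e-04 with an estimated correlation). In Th17p cells the 768 genes lower in iTreg than in Th17n cells had a median of -0.98, with 457 lower and 14 higher (camera p = 3.3e-29, and 4.7e-05 with an estimated correlation). Genes higher in iTreg cells moved less. The 552 genes higher in iTreg than in Th17p cells had a median of 0.35 in Th17n cells, with 148 higher and 77 lower (camera p = 0.020, and 0.0082 with an estimated correlation), and without animal 1 the median was 0.21 (camera p = 0.15). The 632 genes higher in iTreg than in Th17n cells had a median of 0.05 in Th17p cells, with 105 higher and 107 lower (camera p = 0.54, and 0.49 with an estimated correlation). Without scaling factors its median was 0.11. With genes absent from a group set at their bounds the medians were -1.07, -0.99, 0.35 and 0.09. Genes lower in iTreg cells also fell in DFMO-treated iTreg cells, with a median of -0.65 over 348 and of -0.47 over 406 of these genes at 4 CPM or more in vehicle iTreg cells (-0.97 in Th17n and -0.74 in Th17p cells over the same genes).

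The difference between DFMO effects was tested gene by gene. Between Th17n and Th17p cells 303 genes responded more positively in Th17n and 271 less. Il17a (3.63 ± 0.69, edgeR adjusted p = 0.011), Il17f (2.97 ± 0.51, edgeR adjusted p = 0.0073) and Il10 (4.80 ± 0.87, edgeR adjusted p = 0.0039) were among the former. The difference for Foxp3 was 1.82 ± 0.90 and did not pass (edgeR adjusted p = 0.29). Of 16 unfolded protein response genes 6 responded more positively in Th17n cells (8 adjusted over the list alone, camera adjusted p = 2.5e-05, adjusted p = 0.18 with an estimated correlation). Of 24 ribosome biogenesis genes 9 did (16 and 1 less, adjusted over the list alone, camera adjusted p = 5.1e-09, adjusted p = 0.18 with an estimated correlation). The call was lost without animal 1 by Il17a (4.14) and Il17f (3.24), without animal 2 by Il17a (3.56) and Il10 (3.28), and without animal 3 by Il17a (2.99) and Il17f (2.55). The count of genes was 97, 27 and 331 without animals 1, 2 and 3.

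Between Th17n and iTreg cells 628 genes responded more positively in Th17n and 768 less, Foxp3 (3.18 ± 0.44, edgeR adjusted p = 0.00075), Odc1 (0.77 ± 0.19, edgeR adjusted p = 0.013) and Ctla4 (2.09 ± 0.24) among the former. Without animal 1 Foxp3 was not called (3.13), and without animal 2 Odc1 was not called (0.84). Between Th17p and iTreg cells 383 genes responded more positively in Th17p and 406 less (637 and 600 with the animal as a block), with Odc1 at 1.24 ± 0.19 (edgeR adjusted p = 0.00064) and Il17f at -5.57 ± 0.75. The counts were 388 without animal 1 and 277 without animal 2 for Th17n and iTreg cells, and 386 and 107 for Th17p and iTreg cells. Without scaling factors the splits of the 3 differences were 398 more positive and 205 less, 1509 and 450, and 678 and 261, and on log2 TPM 320 and 180, 2161 and 402, and 1014 and 316.

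Sat1 (chromosome X, 155213132 to 155216449) stood apart in animal 2, whatever the lineage or treatment. In animal 2 it lay between 23.9 and 34.1 CPM in the 6 groups, and in animals 1 and 3 between 216 and 498 CPM, while Amd1 reads in that animal were 324 against 294 CPM in the others and those of its paralog Amd2 2.56 against 51.8 CPM. The sum of Amd1 and Amd2 differed by -0.11 in log2 between animal 2 and the others.

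**Figure D4:**
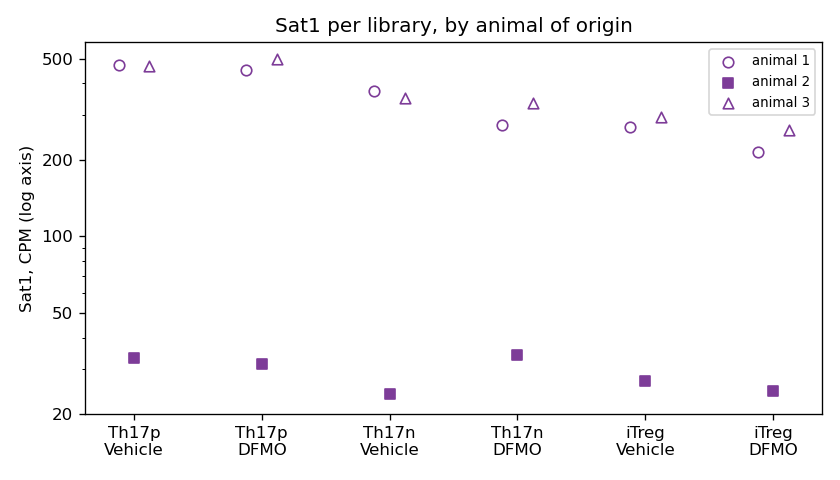
Sat1 in CPM on a log axis in each group, with a marker per animal and animal 2 filled. The libraries of animal 2 lie between 23.9 and 34.1 CPM, below both other animals in all 6 groups.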

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

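The results in this part drew attention because the effect of DFMO differed between lineages by edgeR's test of the difference. The counts over other splits of the libraries were planned, while the look at which draws kept a lineage's treated and vehicle libraries apart was chosen only after the result was seen.

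The effect of DFMO differed between Th17n and Th17p cells for 574 genes. The differences in log2 were Iigp1 5.26, Gcnt2 4.71, Ctla2b 3.84, Il17a 3.63, Pdpn 3.32, Cd86 3.30, Alpk2 3.27 and Il17f 2.97. Among the genes followed throughout they were Il10 4.80, Ctla4 0.93, Amd1 0.57 and Oaz1 -0.43. For Il17a and Il17f the effect was thus more negative in Th17p than in Th17n cells, where neither passed. Each of these 12 genes lost its call in at least 1 of the 3 fits without an animal. Without animal 1 the values that lost the call were Iigp1 5.25, Gcnt2 4.55, Ctla2b 4.40, Il17a 4.14, Pdpn 3.82, Cd86 2.53, Il17f 3.24, Oaz1 -0.40, Amd1 0.53 and Ctla4 1.12. Without animal 2 they were Ctla2b 3.75, Il17a 3.56, Pdpn 2.33, Alpk2 3.24, Oaz1 -0.43, Amd1 0.61, Ctla4 1.06 and Il10 3.28. Without animal 3 they were Iigp1 4.95, Il17a 2.99, Pdpn 3.53, Cd86 3.06, Il17f 2.55 and Oaz1 -0.43, while Ctla4 kept its call at 0.61.

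Between Th17n and iTreg cells the effect differed for 1396 genes. The largest among genes that met the rule for naming were Iigp1 6.13, Timp1 -5.27, Adm -4.75, Il24 -4.36, Tgm2 3.90, Apol7e -3.87, Pdzk1ip1 -3.76 and Gcnt2 -3.72. Among the genes followed throughout the differences were Foxp3 3.18, Ctla4 2.09, Azin1 0.80, Odc1 0.77, Oaz1 -0.29 and Il17f -2.61. With the animal as a block Il17f was not called (edgeR adjusted p = 0.074). Without animal 1 the values that lost the call were Iigp1 6.16, Timp1 -5.35, Apol7e -3.35, Gcnt2 -3.08, Foxp3 3.13, Oaz1 -0.26 and Il17f -2.80. Without animal 2 they were Timp1 -4.41, Il24 -4.18, Tgm2 4.003, Apol7e -3.32, Odc1 0.84, Oaz1 -0.27 and Il17f -1.22, and without animal 3 Tgm2 3.30 and Oaz1 -0.32. Gcnt2 kept its call without animal 2, at -6.39.

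Between Th17p and iTreg cells the effect differed for 789 genes, with Gcnt2 at -8.43, Timp1 at -6.17, Ctla2b at -5.88, Il17f at -5.57, C3 at -5.34, Aqp3 at -5.07 and Pdpn at -5.02. Ramp3 was fitted at 7.22, where a group had only 2 counts, so its size depends on the prior count. Among the genes followed throughout the differences were Odc1 1.24, Ctla4 1.15 and Amd1 -0.69. Without animal 1 the values that lost the call were Ramp3 6.91, Aqp3 -5.18, Pdpn -5.06 and Ctla4 1.07. Without animal 2 they were Ramp3 7.05, Timp1 -4.93, Ctla2b -5.69, Aqp3 -6.62, Pdpn -4.16, Amd1 -0.64 and Ctla4 1.20, and without animal 3 Aqp3 -4.39 and Pdpn -5.62. Odc1, Gcnt2, Il17f and C3 were called in each of these fits. The size for Gcnt2 varied, at -7.63, -11.95 and -8.02 without animals 1, 2 and 3.

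Other splits were taken for these counts, 61 with the real one, in which treatment was reassigned within every lineage. As many genes were called in 4 of 61 splits for Th17n and Th17p (real 574, highest other 1665), in 4 for Th17n and iTreg (1396 and 2718) and in 2 for Th17p and iTreg (789 and 3708). The highest counts lie well above the real ones and point to a structure of the samples. Each draw that called as many kept treated and vehicle libraries apart in at least 1 of the compared lineages. The draw with 3708 genes did so in both, with 1 of them turned. Such draws hold a real effect of DFMO. In the 48, 46 and 46 draws that mixed the libraries of both lineages that effect adds to the spread within groups, and edgeR called at most 0 genes there. The share for Th17p and iTreg is under 0.05, but mixed draws that can hardly call a gene keep it low. No draw holds an effect of DFMO that is equal in both lineages, so the splits cannot decide about chance for these counts.

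The correlations of DFMO effects across genes were as large in 2, 1 and 1 of 61 splits (real 0.706, 0.607 and 0.496, highest other 0.706, -0.429 and -0.496), each a share under 0.05. The other draw as large, for Th17n and Th17p, kept the real grouping of both lineages and thus repeats the real value. The draw at -0.496 for Th17p and iTreg repeats the real value of that pair, with 1 lineage turned and the sign changed. Neither is another split of the compared libraries. A correlation, unlike a count of calls, is not tested against the spread within groups. The shares were not adjusted over the 3 correlations, and mixed draws hold less of the effect of DFMO. These shares therefore do not decide about chance for the correlations. Mixed draws reached at most -0.439, 0.422 and 0.376, and taken animal by animal the correlations were 0.557 ± 0.014, 0.476 ± 0.049 and 0.390 ± 0.060 (SD, n = 3).

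For comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split called 3797, 5352 and 4329 genes for DFMO in Th17p, Th17n and iTreg cells against a highest other of 0, 0 and 5 by edgeR, and each count was as large in 1 of 10 splits. Between vehicle lineages it called 4301 (iTreg and Th17n), 3477 (iTreg and Th17p) and 2303 genes (Th17n and Th17p), also in 1 of 10. Lists called were 10, 8 and 11 for DFMO against a highest other of 10, 11 and 10, with a count as large in 2, 3 and 1 splits, and 8, 10 and 13 between vehicle lineages against 14, 8 and 11, in 4, 1 and 1 splits. Among the splits that part the libraries of all 3 animals the highest were 9, 8, 6, 6, 6 and 6 lists. Other splits thus called many lists while edgeR called at most 5 genes. Each of these splits mixes the compared groups and still holds part of the real difference, which may enter the list test. The mixing also adds to the spread within groups, which lowers the calls of genes. They therefore do not stand for libraries without a difference. The count of lists called with the preset correlation therefore does little to set the real split apart. The medians over genes set apart between iTreg and Th17 cells were as large in 1 of 10 splits, except for genes higher in iTreg than in Th17n cells taken in Th17p cells (3 of 10, real 0.05, highest other -0.06). The others were real -0.98 and highest other 0.31, real 0.35 and -0.14, and real -1.07 and 0.45.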

How the results depend on the processing

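Library totals without scaling factors were chosen only after the result was seen, and the other alternatives were planned. The animal as a block raised the difference between Th17p and iTreg effects to 1237 genes and changed no call of a printed gene or list other than those given with the results. Without the filter the correlations of effects across genes were 0.596 (Th17n and Th17p), 0.525 (Th17n and iTreg) and 0.407 (Th17p and iTreg). Without scaling factors the median over genes higher in iTreg than Th17n in Th17p cells was 0.11. With an estimated correlation camera called 1 list for DFMO in Th17p cells, 0 in Th17n and 0 in iTreg cells (8 and 11 with the preset one), 2 in iTreg against Th17n, 2 in iTreg against Th17p and 4 in Th17n against Th17p. On log2(TPM + 1) the differences held 2563 (Th17n and iTreg) and 1330 genes (Th17p and iTreg), and Oaz1 turned to 0.016 between Th17n and iTreg.

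Leaving out an animal or a library gave 2416 to 3230 genes for DFMO in Th17p, 3902 to 4841 in Th17n and 2488 to 4221 in iTreg cells, and 2784 to 3888 (iTreg against Th17n), 2289 to 3115 (iTreg against Th17p) and 944 to 1996 (Th17n against Th17p) between lineages. The lowest were without animal 2, or animal 1 for iTreg against Th17n. The differences gave 27 to 555, 277 to 1678 and 107 to 1112. Between Th17n and Th17p single libraries lowered it to 377 (Th17p vehicle 3), 328 (Th17p DFMO 1), 328 (Th17p DFMO 3), 354, 284 (Th17n vehicle 1, 2), 368 and 326 (Th17n DFMO 1, 2), and between Th17p and iTreg to 482 (Th17p DFMO 3), 521 (iTreg vehicle 3) and 477 (iTreg DFMO 2). Fits with fewer libraries have less power, and other causes were not tested. The median of genes higher in iTreg than Th17p in Th17n cells was 0.21 to 0.30, and the correlations were 0.649 to 0.663, 0.548 to 0.586 and 0.429 to 0.477. DESeq2 called 3600 of 3797, 5245 of 5352 and 4302 of 4329 genes that edgeR called for DFMO in Th17p, Th17n and iTreg cells.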

Other observations

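The interferon test on markers of myeloid cells, the tests on chromosome segments and on a mislabelled library, the look at Sat1 beside it, and the list of ribosomal protein genes were chosen only after the result was seen.

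Of 83 tested genes of ribosomal proteins, 73 rose and 1 fell with DFMO in iTreg cells, with a median log2 fold change of 0.45 (54 and 1 without scaling factors, median 0.29), 27 rose and 1 fell in Th17p cells (median 0.18), and 10 rose and 15 fell in Th17n cells (median -0.05). Ribosomal protein genes held 12.1% ± 0.35 (SD, n = 3) of counts in vehicle and 14.7% ± 0.73 in DFMO iTreg cells (exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). Between vehicle cells 28 were higher and 2 lower in Th17n than in Th17p cells (12 and 2 without scaling factors, medians 0.24 and 0.17), and 2 higher and 44 lower in iTreg than in Th17n cells (3 and 15 without scaling factors, medians -0.28 and -0.13).

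Genes lower in iTreg than in a Th17 lineage fell on balance with DFMO in the other Th17 lineage (medians -1.07 in Th17n and -0.98 in Th17p cells). They may fall in every lineage rather than mark a shift towards iTreg cells. Over the 348 and 406 of them at 4 CPM or more in vehicle iTreg cells, the medians were -0.65 and -0.47 in DFMO-treated iTreg cells (196 and 197 lower, 26 and 40 higher), against -0.97 in Th17n and -0.74 in Th17p cells. Choosing genes that are low in vehicle iTreg cells would bias the iTreg medians upward, and GC content and transcript length do not account for the Th17 medians, which were -1.05 and -0.96 after correction. A shared response to DFMO therefore stays open beside a change of fate.

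Of 30 interferon response genes, 27 fell with DFMO in Th17p, 17 in Th17n (1 rose) and 24 in iTreg cells (medians -2.60, -1.68 and -1.82), although the camera call was lost with an estimated correlation (adjusted p = 0.30, 0.52 and 0.23). RNA of contaminating myeloid or plasmacytoid cells is unlikely as the main source by the markers taken. Summed markers (Lyz2, Csf1r, Cd14, Itgam, S100a8, S100a9 and Siglech) reached at most 0.024% of the interferon sum in a vehicle group, 0.714 of 2968 CPM in Th17p cells. Cst3, the highest myeloid marker, was not among them. It stood at 118, 112 and 103 CPM in vehicle Th17p, Th17n and iTreg cells, so such RNA is not fully excluded. No animal alone makes the pattern in Th17p and iTreg cells, where without any 1 animal at least 18 and 22 of 30 genes were called lower. In Th17n cells at least 10 were called lower, with 26 of 30 below 0 in each fit. The pattern is thus less firm there. After correction for GC content and transcript length the highest median of a lineage was -1.71. A lower interferon signal in DFMO-treated cells is an untested hypothesis, which interferon measured in such cultures could decide.

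Between animal 2 and the mean of the other animals 64 genes differed, 30 higher and 34 lower, against 146 genes for animal 1 and 410 for animal 3, and for some, such as Acvrl1 (1.86, 1.96 and -3.82 for animals 1, 2 and 3), it is animal 3 that stands apart. The genes of animal 2 may lie in part on chromosome segments that differ between the animals: 16 neighbouring pairs lay within 2 Mb, against a median of 5 over permutations (permutation p = 1e-04, the smallest that 10000 permutations can give), and 12 pairs among 58 genes without overlapping or repeated copies (permutation p = 0.0024). The genes of animals 1 and 3 showed no excess over all chromosomes (27 and 139 pairs, permutation p = 0.5 and 1). With so many genes such a count can miss a single segment. Kmt2d and Tuba1c, a pair of animal 2 on chromosome 15, stood further apart in animal 3. They were at 0.19 and -0.40 for animal 2 and at -0.39 and 0.73 for animal 3, and Serhl was at 0.45 and -1.07. Some pairs of animal 2 may thus come from animal 3. Equal numbers of the top DFMO genes of iTreg cells gave 7 pairs for the set of animal 2 (permutation p = 0.307) but 37 and 177 for the larger sets (permutation p = 0.011 and 0.0050), so neighbours also exceed random draws without such segments. On genes called in the other 5 groups without Sat1, the library of animal 2 scored above both others by 0.68 to 1.16 in 5 groups and by 0.063 ± 0.127 (SE over genes) in vehicle Th17p cells. Sat1, at 33.1 CPM there against 473 and 470 in animals 1 and 3 and at most at 0.124 of the lowest other library in any group, argues against an exchange with either of them. As a single top gene of the pattern it excludes nothing, so a mislabelled library stays open there, and exchanges between animals 1 and 3 were not tested. Reads shared with the paralog Sat2 do not account for Sat1, whose sum with Sat2 differed by -3.56 in log2. Sat2 held only 0.020 CPM in animal 2 and 0.016 CPM in the others. Sharing of reads with genes that are not listed was not tested. For Amd1 and Amd2, whose summed CPM differed by -0.11 in log2, the sum cannot decide. Amd1 held most of it in the other animals (294 CPM, against 51.8 CPM for Amd2). A lower level of Amd2 alone would therefore also change the sum little. No biological explanation was tested.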
